A study of Mus musculus with 30 samples.

How the data were processed

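Cerebellar RNA from 30 female mice was measured, each mouse on 1 2-colour Agilent array. Knock-in (KI) mice, which per the labels model spinocerebellar ataxia 7 (SCA7), and wild-type (WT) mice were sampled at postnatal day 10 (P10), at P22 and at week 11. The groups held 5 KI and 5 WT mice at P10, 4 KI and 5 WT mice at P22, and 6 KI and 5 WT mice at week 11. The authors killed P10 and P22 mice by decapitation and week 11 mice by cervical dislocation, so week 11 differs from the earlier ages in that step too. Each mouse's amplified RNA was labelled with Cy5, and every array also carried 1 common reference in Cy3, a pool made from the P10 animals of both genotypes. No dye was swapped.

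Per the file headers, the scanner files hold spot signals and local backgrounds as intensity values, together with Agilent Feature Extraction 9.5.3.1 log ratios of Cy5 over Cy3 in log10 and 0 or 1 flags in a unit recorded as other. The deposited value table holds log2 ratios that the authors normalised in BRB-ArrayTools by a method they do not name. It covers 1905 probes, 4 of them control features, and has 48 missing values. Its values run in the opposite direction to the scanner files, reference over sample: across arrays their correlation over probes with the log2 ratio of Cy5 to Cy3 without background subtraction lay between -0.9997 and -0.9613. The medians of its columns ran from 0.0679 to 1.1428, so the centring the authors used stays unknown. Here that table serves only as an alternative, and the comparisons start from the scanner intensities. Every column of the table belonged to a sample.

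Each array has 45018 spots, of which 1639 are controls. The remaining 43379 spots carry 41174 probes, 245 of them on 10 spots each. Spots flagged as outliers, between 0.81% and 10.16% of an array, were set to missing. In limma 3.58.1 under R 4.3.3, backgrounds were corrected by normexp with an offset of 50, log2 ratios of Cy5 to Cy3 were normalised within each array by loess, and spots of the same probe were averaged. A probe counted as detected where Cy5 was well above background on at least 4 of the 30 arrays, which left 35598 probes for 20204 named genes. Of these genes, 7545 had more than 1 detected probe. Symbols were looked up through the accession in the files for 22944 probes, taken from the files for 11765, and missing for 6465. The looked-up symbol differed from the one in the file for 5139 probes. The lookup table belongs to assembly GRCm38.p6, while the array was annotated on build mm7, so no base positions are given.

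A linear model with 6 group means was fitted to all 30 arrays, with moderated statistics by limma on 24 residual and 3.97 prior degrees of freedom. P values, two-sided, were adjusted by the Benjamini-Hochberg method over the probes of a comparison, with a threshold of 0.05. The comparisons were KI against WT at each age and averaged over ages, the change of that difference between neighbouring ages, the interaction of genotype and age as an F test, and the steps from P10 to P22 and from P22 to week 11 in WT. A comparison was tested only where each group in it had at least 3 usable arrays; 2484 detected probes fell short in at least 1 group. That minimum was set after a first fit in which a probe of Prdm8, with 1 usable array per genotype, had passed at P10. The interaction was also read by the criterion in the series record: Cy5 well above background on at least 50% of arrays, at least 20% of arrays 2-fold or more from the probe's median, and unadjusted p under 0.001. Limma's moderation stood in for the random variance model named there.

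The 23 gene lists, holding 373 distinct genes of which 4, Itpr1 among them, stand in 2 lists, were written before the data were examined, as were the model, the thresholds and the rule for naming genes. They cover Purkinje cells, granule neurons, granule precursors with Sonic hedgehog signalling, the cell cycle, inhibitory interneurons, Bergmann glia with astrocytes, myelin, oligodendrocyte precursors, microglia, the interferon response, cytosolic heat shock, unfolded protein and amino acid stress, the SAGA complex, other ataxia genes, oxidative phosphorylation, cholesterol synthesis, insulin-like growth factors, immediate early genes, erythrocytes, choroid plexus, brainstem with deep nuclei, endothelium, and meninges with fibroblasts. Of 377 entries, 366 were measured. Lists were tested by camera with a preset correlation of 0.01 between genes, on the brightest probe of each gene, with adjustment over the 23 lists. Camera with an estimated correlation and fry were run beside it. A list's value is the mean over its members of the difference between group means, and KI or WT values with SD are means over mice.

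Genes named in a comparison of genotypes were the 10 with the largest rise and the 10 with the largest fall that passed, or, where none passed, the 5 with the smallest p. The WT steps name the 10 largest rises and 10 largest falls. Atxn7 and the 3 members with the smallest p of each described list were named too, except that some of these members are not reported here. For Atxn7, an exact two-sided permutation test was run within each age. Whether genotype differences follow normal maturation was read from the correlation over genes between KI minus WT at 1 age and the WT step between the other ages, set against 100 permutations of genotype within age.

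The alternatives were no background subtraction, an offset of 16, Agilent's own log ratio, median centring, scale normalisation between arrays, Cy5 alone, other detection filters, an ordinary linear model, array weights, slide as a block, scan day as a block for single probes, only the arrays compared, genes in place of probes, the authors' table, and leaving out each mouse. Alternatives added later were scan day as a block for the gene lists, slide as a block for Atxn7, no minimum of usable arrays, keeping spots flagged as outliers, slide as a random block, and leaving out mice 1 to 4, mice 7 and 8, mice 20 and 21, or mice 7, 8, 20 and 21. The arrays came on 8 slides. At P22 only slide 7 held both genotypes, with 1 mouse of each, and slide 6 held the other 4 WT mice. Array pairs on a slide had a consensus correlation of 0.427.

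The smallest correlation between the log ratios of any 2 arrays was -0.366 and the smallest within a group was -0.341, both over detected probes. Because the methods name the dye of each sample, every array kept its direction. On simulated data with independent probes and the spread of these arrays, the model recovered 83.6% of 2-fold changes at P10 and at P22, 85.1% at week 11 and 97% averaged over ages, and 34.3% of 1.41-fold changes at P10. The number of arrays limits the precision. On such data camera called a list in 1 of 20 sets without a change and the interferon list in 20 of 20 with a log2 rise of 0.4. The simulated genes were independent and slides had no effect, so these rates do not carry over to the arrays here. Of 100 groupings of the P10 mice, the real one included, 92 called at least 3 lists. Splits of the same mice into groups of the same sizes were counted, 100 at most per comparison. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, statmod 1.5.0 and the R package data.table in version 1.17.8 were used besides.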

Results

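Expression in the cerebellum was measured in 30 female mice, 15 KI and 15 WT, on 1 array per mouse. The KI mice model SCA7, an inherited ataxia caused by a repeat expansion in Atxn7, whose protein belongs to the SAGA chromatin complex. There were 5 KI and 5 WT mice at P10, 4 KI and 5 WT at P22, and 6 KI and 5 WT at week 11. The Cy5 signal of the mouse was well above background for 67.7% to 89.7% of an array's spots, with a median of 77.35%, and the Cy3 signal of the common reference for 70.2% to 86.4%. The median spot signal per array ran from 135.1 to 551.6 in Cy5 over local backgrounds of 40 to 49, and from 208.7 to 578 in Cy3 over backgrounds of 39 to 58.5. All differences below are log2 differences of the ratio of mouse to reference, with the standard error of the limma fit after ±, and n is the number of mice in a group, of which a single gene with unusable spots rests on fewer, at least 3.

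Atxn7, the targeted gene, was read by 1 detected probe. That probe reports total expression and does not show which allele is expressed. At P10 the log2 ratio was -0.47 ± 0.08 (SD, n = 5) in KI and -0.21 ± 0.41 (SD, n = 5) in WT mice, a difference of -0.26 with an exact permutation p of 0.206. At P22 it was 0.13 ± 0.27 (SD, n = 4) in KI and 0.69 ± 0.40 (SD, n = 5) in WT mice, a difference of -0.56 with an exact permutation p of 0.0476, 3 of 4 KI mice lying below every WT mouse. At week 11 it was 0.61 ± 0.38 (SD, n = 6) in KI and 0.76 ± 0.33 (SD, n = 5) in WT mice, a difference of -0.16 with an exact permutation p of 0.491. The P22 difference did not pass the exact test without KI replicate 12 or 13 (p = 0.125 each), KI 17 (0.0893), WT 26, 27 or 30 (0.0857 each) or WT 29 or 31 (0.0571 each), leaving KI 11 as the 1 mouse without which it passed (-0.67), and the P10 difference passed without WT 7 (-0.39, p = 0.0238) and was -0.12 without WT 5. The week 11 difference was -0.03 without KI 21, -0.07 without WT 23, -0.24 without KI 22 and -0.28 without WT 32. The smallest p that each test allowed was 0.00794, 0.0159 and 0.00433. Over all probes the limma adjusted p was 0.706 at P10, 0.415 at P22 and 0.999 at week 11, so no age passed. With slide as a block the P22 difference was -1.19 with a limma adjusted p of 0.0351, and the differences at P10 and week 11 were -0.26 and -0.29. The blocked P22 value rests on WT 26 for the WT side, since slide 6 held only WT P22 mice. On slide 7 KI 17 and WT 26 differed by -1.11. WT 26 was at 1.37, where the other WT P22 mice lay at 0.41 to 0.70. From the Cy5 channel alone the P22 difference was -0.15, within the spread between mice.

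**Figure D1:**
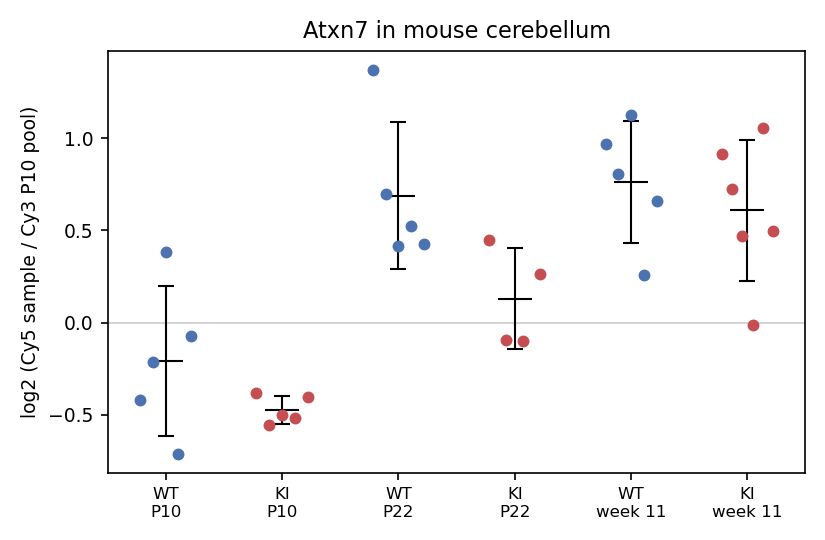
Log2 ratio of Atxn7 to the common reference, per mouse, by genotype and age; bars are the mean and SD of 4 to 6 mice. WT mice lie higher at P22 (mean 0.69) than at P10 (mean -0.21), and the KI mean at P22 is 0.13.

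The step from P10 to P22 in WT mice shows what the cerebellum does while granule cells stop dividing and mature, and it is the course against which KI mice are set. Cbln3, a granule cell synaptic protein, rose by 3.62 ± 0.63 and Gabra6, a GABA-A receptor subunit of granule cells, by 3.38 ± 0.76 (n = 5 and 5), though neither passed with slide as a block. Ccnb1, cyclin B1, fell by 3.87, Aurkb, a mitotic kinase, fell by 3.45, and Mki67, a proliferation marker, fell by 3.22. Itpr1, the calcium release channel abundant in Purkinje cells, rose by 3.16 ± 0.63. Camera called the lists of granule neuron, Purkinje cell and cell cycle genes at its preset correlation and none of the 3 with an estimated one (adjusted p = 0.224, 0.423 and 0.224). With an estimated correlation it called 0 of the 23 lists here, where fry called 14 and most cell cycle genes passed singly. It called 0 in every other comparison too. Its lack of calls alone therefore does not show that a list is unchanged. Atxn7 itself rose by 0.90 ± 0.20 with a limma adjusted p of 0.00132.

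In this step limma called 10444 of 34826 probes, 5010 higher and 5434 lower at P22, for 6502 genes. Of these probes 2083 changed more than 2-fold. The largest rises besides Cbln3, Gabra6 and Itpr1 were Etnppl at 18.6-fold, Fam107a at 13.6-fold, the immediate early gene Fos at 10.3-fold, Crtam at 9.77-fold, Olfm3 at 7.79-fold, the metallothionein Mt2 at 6.64-fold and LOC629147 at 6.56-fold. The largest falls besides Ccnb1, Aurkb and Mki67 were Tox3, Pbk, Spc25, Cenpa, Uhrf1, Sox11 and Esco2, with log2 changes from -3.76 for Tox3 to -3.18 for Esco2. No slide held WT mice of both ages, so a blocked value rests on KI arrays that link the slides. Slide 6 and its scan day held only WT P22 mice, so with either block the WT P22 side rests on WT 26. That array had the lowest array weight, 0.261. Calls lost or gained in the blocked fits therefore cannot be told apart from the values of that 1 mouse. A fit with slide as a block called 5293 probes, and Fam107a (0.29, adjusted p = 0.87), Gabra6 (1.56, adjusted p = 0.456), Cbln3 (2.34, adjusted p = 0.128), Crtam (1.96, adjusted p = 0.064) and Mt2 (1.87, adjusted p = 0.114) no longer passed. Of the 49 genes named in this step 17 lost their call with slide as a block and 24 with scan day as a block, the latter being those 17 and Fos, Itpr1, Aurkb, Mal, Gpr17, Fgf14 and Mvk, and 1 more, Uqcrc2, turned direction and lost its call in both. Scale normalisation ended the calls of Itpr1, Cspg2 and Fgf14, median centring those of Sdha, Uqcrc1 and Uqcrc2, and the Cy5 channel alone those of Aspa, Kcnd3, Sdha and Uqcrc1 and turned Uqcrc2.

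Among the gene lists, camera called 10 in this step. Granule neuron markers were higher by 1.92 on average, 9 of 13 measured members called over all probes and 10 adjusted over the list alone, among them Tiam1 (2.19 ± 0.21), Chn2 (2.16 ± 0.21) and Calb2 (2.29 ± 0.29). Purkinje cell markers were higher by 1.04, with 14 of 24 called higher and 1 lower, and 17 higher and 2 lower adjusted over the list alone; Atp2a3 (1.32), Plcb4 (1.44) and Kcng4 (1.59) were among them. Cell cycle genes had a mean of -2.26, with 19 of 20 called lower over all probes and 19 adjusted over the list alone, including Tpx2 (-2.58), Plk1 (-1.80) and Aurkb. The adjusted p values were 3.78e-07, 8.1e-06 and 8.19e-15, and with an estimated correlation adjusted p = 0.224, 0.423 and 0.224. Immediate early genes, which respond to neuronal activity, had a mean of 1.15 (9 called higher, 1 lower; the same counts adjusted over the list alone), with Dusp1 at 2.22, Egr1 at 1.93 and Nr4a1 at 2.42. Interferon response genes had a mean of 0.68 (9 higher, 1 lower; the same adjusted over the list alone), with Ifit3 at 2.06, Ifit1 at 2.08 and H2-K1 at 0.77. Other ataxia genes had a mean of 0.59 (9 higher, 1 lower; 10 and 1 adjusted over the list alone), with Kcnd3 at 0.53, Fgf14 at 0.91 and Itpr1, which also stands in the Purkinje list. The adjusted p values were 4.49e-05, 0.000327 and 0.00551, and with an estimated correlation adjusted p = 0.224, 0.498 and 0.224. Blocking on slide, Atp2a3 (adjusted p = 0.104), Plcb4 (0.205), Kcng4 (0.408), Ifit1 (0.384) and H2-K1 (0.372) no longer passed.

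Camera at its preset correlation also called the lists of cholesterol synthesis, oligodendrocyte precursor, myelin and oxidative phosphorylation genes in the same step, and none of them with an estimated correlation (adjusted p = 0.336, 0.336, 0.589 and 0.498). Cholesterol synthesis genes had a mean of -0.54, 12 of 19 called lower and 13 adjusted over the list alone, among them Nsdhl (-1.12), Mvk (-0.79) and Dhcr7 (-1.21). Oligodendrocyte precursor markers had a mean of -1.08, 3 of 5 called lower and 4 adjusted over the list alone, with Pdgfra at -1.58, Gpr17 at -1.76 and Cspg2 at -0.86. Myelin genes had a mean of 0.55, 4 of 20 called higher and 4 adjusted over the list alone, with Mal at 2.34, Aspa at 1.45 and Opalin at 1.49. Oxidative phosphorylation genes had a mean of 0.20, 5 of 19 called higher and 5 adjusted over the list alone, with Sdha at 0.66, Uqcrc1 at 0.49 and Uqcrc2 at 0.44. The adjusted p values at the preset correlation were 4.49e-05, 0.0107, 0.013 and 0.0298. Fry called 14 lists, not myelin genes among them (adjusted p = 0.0729). In the fit with slide as a block Aspa (adjusted p = 0.16), Opalin (0.462), Pdgfra (0.0547), Cspg2 (0.408), Dhcr7 (0.558), Sdha (0.274) and Uqcrc1 (0.398) no longer passed, and Uqcrc2 turned to -0.04 (0.938). That fit also called interneuron markers (0.66, adjusted p = 0.0333), erythrocyte genes (1.72, 0.0275) and choroid plexus genes (-2.33, 0.0275). With slide as a block the adjusted p of cholesterol synthesis was 0.0961, of myelin 0.05, of oligodendrocyte precursors 0.149 and of oxidative phosphorylation 0.703, whose mean turned to -0.08 with median centring; with scan day as a block the adjusted p of Purkinje cell markers was 0.328, of myelin 0.0701, of precursors 0.407, of oxidative phosphorylation 0.855 and of cholesterol synthesis 0.0865, and interneuron markers were called (0.64, adjusted p = 0.0469). The myelin call ended without WT replicate 5 (adjusted p = 0.0711) or 7 (0.0536) and with median centring (0.052), and that of oxidative phosphorylation without WT replicate 5 (0.0734), 27 (0.0646) or 29 (0.0605) and from the Cy5 channel alone (0.291). Without the 4 mice of slide 1 the calls of precursors (0.117) and oxidative phosphorylation (0.0726) ended.

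**Figure D2:**
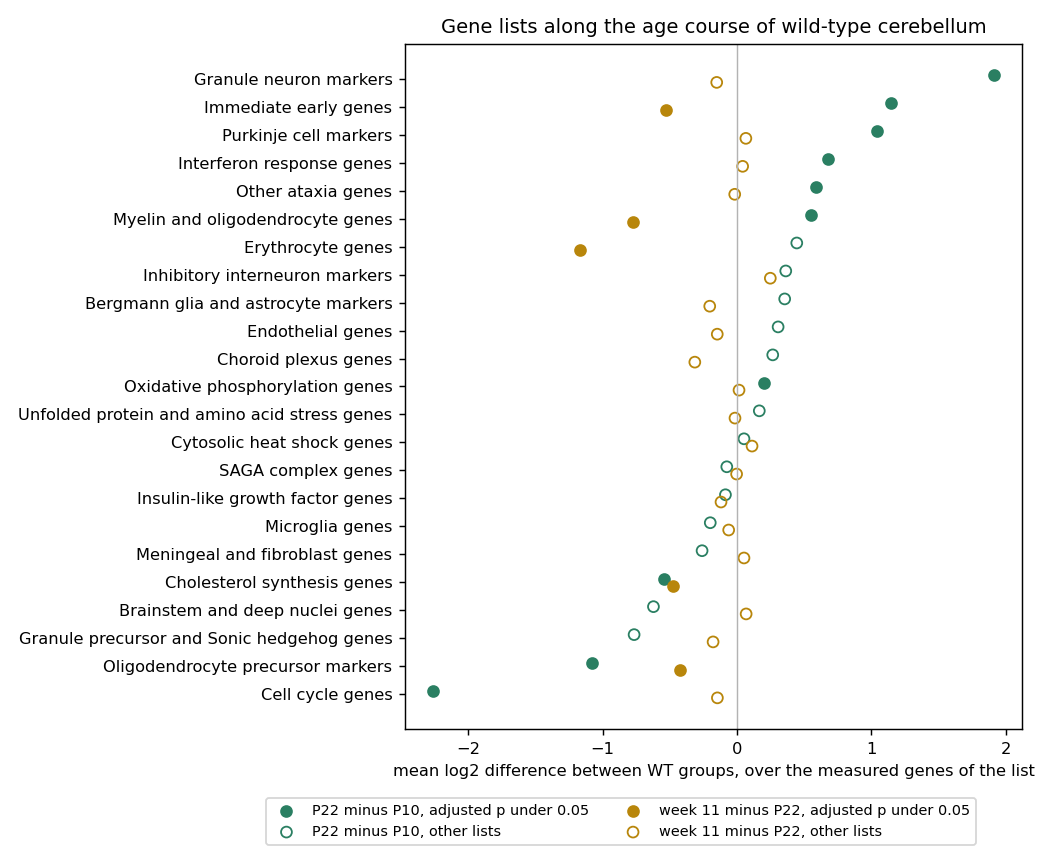
Mean log2 difference of each of the 23 gene lists between WT groups, P22 minus P10 and week 11 minus P22, over the measured genes of a list (5 mice per age); filled points have a camera adjusted p under 0.05. From P10 to P22 granule neuron markers were at 1.92 and cell cycle genes at -2.26. Oxidative phosphorylation genes, filled at 0.20 in that step, turn to -0.08 with median centring.

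From P22 to week 11 in WT mice, camera at its preset correlation called lower means in the lists of myelin, cholesterol synthesis and immediate early genes, and none of them with an estimated correlation (adjusted p = 0.363, 0.0874 and 0.363). The myelin proteins Mal and Cldn11 changed by -1.80 ± 0.33 and -1.78 ± 0.34, and Cyp51, Sqle and Idi1, enzymes of cholesterol synthesis, changed by -1.10 ± 0.15, -0.85 ± 0.16 and -0.75 ± 0.15. Mela rose by 2.31 ± 0.13 and Serpinb2 fell by 2.80 (n = 5 and 5). The week 11 mice were also killed in another way than the P22 mice.

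Limma called 597 of 35087 probes in this step, 320 higher and 277 lower at week 11, for 447 genes. Of these probes 85 changed more than 2-fold. The other large rises were Kazald1 (1.55), the cytokine Il33 (1.42), xanthine dehydrogenase Xdh (1.42), Aass (1.37), Efemp1 (1.37), Apol2 (1.35), Jade2 (1.27), AW112010 (1.23) and Gpat3 (1.20). The other large falls were Rhbdf2 (-2.42), Slc4a7 (-1.96), LOC673334 (-1.88), Ptprz1 (-1.87), the haemoglobin chaperone Eraf (-1.79, adjusted p = 0.05), Enpp6 (-1.56) and Sh3gl3 (-1.55). The count was 251 without WT P22 replicate 30, 329 without WT P22 replicate 31, 267 without WT week 11 replicate 32, 324 without WT week 11 replicate 33 and 905 without WT P22 replicate 26. The call of Eraf ended without any 1 of the 10 mice (adjusted p = 0.054 to 0.138), and that of Jade2 without WT replicate 27 (0.0619), 29 (0.0764), 30 (0.0724), 31 (0.0706), 32 (0.0663) or 33 (0.0867). Calls also ended for LOC673334 without WT 29 (0.0524) or 32 (0.0624), for AW112010 without WT 30 (0.0756), 31 (0.0651) or 32 (0.0661), and for Ptprz1 without WT 30 (0.052) or 32 (0.057). Fits with slide or scan day as a block take the WT P22 side from WT 26, since slide 6 held only WT P22 mice. Calls lost or gained in them cannot be told apart from the values of that 1 mouse. When slide was a block, Il33 (adjusted p = 0.0881), Jade2 (0.469), LOC673334 (0.435), Ptprz1 (0.0595), Eraf (0.1), Idi1 (0.125) and Npas4 (0.359) no longer passed, and Gpr17 (adjusted p = 0.0214), Olig1 (-1.10, 0.012) and Alas2 (-2.62, 0.021) did. With scan day as a block 18 of the 34 genes named in this step lost their call, those 7 and Kazald1, Aass, Apol2, AW112010, Gpat3, Mal, Cldn11, Enpp6, Sh3gl3, Tspan2 and Cyp51. Scale normalisation gave 81 probes and ended the calls of 17 of these 34 genes, Il33, Aass, Jade2, Gpat3, Slc4a7, LOC673334, Ptprz1, Mal, Eraf, Cldn11, Enpp6, Sh3gl3, Tspan2, Cyp51, Sqle, Idi1 and Npas4. Median centring ended those of 7, Mal, Eraf, Cldn11, Tspan2, Cyp51, Sqle and Idi1, and the Cy5 channel alone those of Jade2, Eraf, Idi1 and Npas4. Array weights gave 2743 probes.

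Camera called 5 lists in this step. Cholesterol synthesis genes had a mean of -0.47, with 19 of 20 members lower, 5 called over all probes and 15 adjusted over the list alone (adjusted p = 1.01e-14; adjusted p = 0.0874 with an estimated correlation). Myelin genes had a mean of -0.77, with 18 of 20 lower, 4 called and 8 adjusted over the list alone, among them Tspan2 at -1.27 (adjusted p = 1.46e-10; 0.363 with an estimated correlation). Immediate early genes had a mean of -0.53, with 1 of 14 called lower over all probes, Npas4 (-1.26 ± 0.34, adjusted p = 0.0494), and 6 lower and 1 higher adjusted over the list alone; Nr4a1 was at -1.37 ± 0.38 and Fos at -1.92 ± 0.53. Erythrocyte genes had a mean of -1.17, with 0 of 4 called by limma over all probes and 2 adjusted over the list alone; Slc4a1 was at -1.14, Alas2 at -1.87 and Hbb-bt at -0.74. Oligodendrocyte precursor markers had a mean of -0.43, with 0 of 6 called by limma over all probes and 1 adjusted over the list alone; Gpr17 was at -0.91, Cspg2 at -0.50 and Olig1 at -0.46. The adjusted p values of these 3 lists were 0.000613, 0.00112 and 0.0258, and with an estimated correlation adjusted p = 0.363, 0.363 and 0.534. The call of Npas4 ended without WT replicate 18 (adjusted p = 0.117), 20 (0.138), 26 (0.0643), 27 (0.0795), 29 (0.0521), 30 (0.143), 31 (0.104), 32 (0.0712) or 33 (0.0623), and that of Tspan2 without WT 30 (0.0564). The precursor call ended without WT P22 replicate 26 (adjusted p = 0.0966) or WT week 11 replicate 23 (0.0553) or 32 (0.0521). With median centring the adjusted p of cholesterol synthesis was 0.105 and of precursors 0.302, that of precursors was 0.11 from the Cy5 channel alone and 0.195 with the mean of all probes of a gene, with slide as a block that of immediate early genes was 0.0595, and with scan day as a block that of erythrocyte genes was 0.0666. With slide as a block other ataxia genes were at -0.31 and choroid plexus genes at -1.28, and with scan day as a block other ataxia genes were at -0.31. In both blocks the WT P22 side rests on WT 26. That mouse was at 0.65 in other ataxia genes, where the other WT P22 mice lay at 0.265 to 0.368.

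At P10, the youngest age sampled, KI mice had lower means in lists of meningeal, granule neuron and cell cycle genes by camera at its preset correlation, and in none of them with an estimated correlation (adjusted p = 0.891 each). The granule neuron list differed by -0.47, with Chn2, a Rac GTPase-activating protein, at -0.90 ± 0.24, the granule lineage factor Zic1 at -1.32 ± 0.48 and Cbln3 at -0.94 ± 0.63. The cell cycle list differed by -0.25, with Ccnb1 at -0.97 ± 0.45, Mcm3 at -0.37 ± 0.29 and Aurkb at -0.53 ± 0.44. The meningeal list differed by -0.34, with all 10 members lower, among them Ogn (-0.62 ± 0.28), Slc6a13 (-0.51 ± 0.31) and Col3a1 (-0.39 ± 0.28). No single gene passed (n = 5 and 5, with 3 usable KI mice for Chn2, 4 for Slc6a13, and 3 usable mice in a group for Ccnb1). Most of these gene values depended on single mice, and for Chn2 and Ccnb1 this could not be tested in full. With 1 mouse left out, Chn2 stayed at -0.97 to -0.74 and Ccnb1 at -1.25 to -0.69 over 7 fits each. Their other fits left a group under 3 usable mice, so the mice of that group were never left out. On slide 1 Chn2 differed by -1.62 and Ccnb1 by -1.21, against -0.31 and -0.43 on slide 2. Without KI replicate 4, Zic1 was at -0.83, Cbln3 at -0.43, Mcm3 at -0.18, Aurkb at -0.32, Ogn at -0.39, Slc6a13 at -0.15 and Col3a1 at -0.17, and without KI 3, Cbln3 was at -0.55, Mcm3 at -0.21, Ogn at -0.34, Slc6a13 at -0.31 and Col3a1 at -0.25. Without WT 5, Mcm3 was at -0.15, Aurkb at -0.29 and Col3a1 at -0.24, without WT 7 Mcm3 at -0.16 and Aurkb at -0.25, and without WT 10 Cbln3 at -0.49. Larger differences came without WT 1 for Cbln3 (-1.66), Mcm3 (-0.69) and Aurkb (-0.92), without KI 6 for Slc6a13 (-0.83), without KI 8 for Mcm3 (-0.56) and without KI 9 for Cbln3 (-1.45).

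Limma called 0 of 34832 probes at P10, where 2897 had an unadjusted p under 0.05 and chance gives 1742. Among genes, with 1 probe each, the smallest p values belonged to Cnep1r1 (-0.63), 7530403E16Rik (1.03), Snapc2 (0.47), the synaptic vesicle protein Vamp1 (1.09) and the nucleoporin Nup88 (-0.65), all with an adjusted p of 0.577. Nup88 had 3 usable KI and 3 usable WT mice, Vamp1 had 4 and 3, and 7530403E16Rik had 4 usable KI mice. In a fit with slide as a block, each P10 slide holding as many KI as WT mice, Cnep1r1 (-0.56, adjusted p = 0.0335), 7530403E16Rik (0.76, 0.0187), Snapc2 (0.47, 0.0302) and Nup88 (-0.53, 0.0358) passed and Vamp1 (0.79, 0.089) did not. By camera the adjusted p was 0.0147 for meningeal genes, 0.0154 for granule neuron markers (10 of 12 lower, 1 adjusted over the list alone) and 0.0338 for cell cycle genes (19 of 21 lower), with adjusted p = 0.891 with an estimated correlation in each. Over all probes limma called 0 of their members, and adjusted over the list alone 0 for the meningeal and cell cycle lists.

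These 3 differences were largest on slide 1 (KI 3 and 4, WT 1 and 2). There the lists differed by -0.75, -1.04 and -0.36, against 0.10, -0.22 and -0.21 on slide 2 and -0.16, -0.12 and -0.04 on slide 3, and with slide as a block the means were -0.34, -0.50 and -0.25 and all 3 passed (adjusted p = 0.00747, 0.0109 and 0.000838); with scan day as a block cell cycle genes did not (-0.26, 0.0677). Without the 4 mice of slide 1 they were -0.05, -0.25 and -0.17 (adjusted p = 0.729, 0.349 and 0.349). Meningeal genes lost their call without KI replicate 3 (-0.18, adjusted p = 0.464) or 4 (-0.13, 0.361). Granule neuron markers lost it without KI replicate 3 (-0.18, 0.464), 4 (-0.19, 0.447) or WT replicate 10 (-0.25, 0.248), and at a similar mean without KI 6 (-0.48, 0.0565) or WT 2 (-0.41, 0.05); their mean was -0.80 without KI 9 and -0.86 without WT 1. Cell cycle genes lost it without KI replicate 3 (-0.04, 0.95) or 4 (-0.09, 0.586) or WT replicate 5 (-0.002, 0.916) or 7 (-0.03, 0.677), and their mean was -0.43 without KI 6, -0.49 without KI 8 and -0.53 without WT 1. Brainstem genes (0.42, 18 of 19 higher, adjusted p = 0.0575), Purkinje cell markers (-0.24, adjusted p = 0.0575) and myelin genes (0.25, adjusted p = 0.105) were not called, and all 3 were with slide as a block (0.43, -0.24 and 0.235, adjusted p = 0.0134 each). Median centring ended all 3 calls (adjusted p = 0.208, 0.0855 and 0.217), the mean of all probes of a gene those of granule neuron (0.101) and cell cycle genes (0.0583), and slide as a block gave 589 called probes.

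At P22 no gene and no list passed the test between KI and WT mice in the main fit. The genes with the smallest p values, at 1 probe each, were Lig4, a DNA ligase (0.51 ± 0.10), Kdf1 (higher in KI), Marchf11 (-0.80 ± 0.17), Mcub, a subunit of the mitochondrial calcium uniporter (0.84 ± 0.17), and Ear3 (0.51 ± 0.11), with all 4 KI mice beyond every WT mouse for each. Kdf1 was not well above background on any WT P22 array, which allows only a statement of at least 1.12-fold. Of the lists, cytosolic heat shock genes had the smallest adjusted p, 0.314, at a mean of 0.20.

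Limma called 0 of 33250 probes at P22, with 3176 at an unadjusted p under 0.05 where chance gives 1662. The adjusted p was 0.191 for Lig4, 0.211 for Kdf1, Marchf11 and Mcub, and 0.226 for Ear3, and the smallest over all probes was 0.19. Other settings did call genes. Of the 6 genes named at P22, Atxn7 included, 5 passed with array weights (875 probes called) and 3 from the Cy5 channel alone (3853 probes). Slide and genotype were nearly the same split at P22, and the single pair on slide 7 differed by -0.51 in granule neuron markers, 0.46 in brainstem genes and -0.32 in interferon response genes. A fit with slide as a block called 2371 probes, 495 higher and 1876 lower, among them Marchf11 (-1.08, adjusted p = 0.00588) and Mcub (1.38, adjusted p = 0.00875) but not Lig4 (0.22, 0.457), Ear3 (0.68, 0.0509) or Kdf1 (adjusted p = 0.136, without a size), on the evidence of that pair and of the other ages on shared slides.

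At week 11, the oldest age sampled, camera at its preset correlation called a higher mean of interferon response genes in KI mice and lower means of cholesterol synthesis, Purkinje cell, Bergmann glia, myelin and choroid plexus genes. With an estimated correlation it called 0 of these 6 lists, the smallest adjusted p being 0.285. All 21 interferon genes were higher, by 0.44 on average, with the antigen transporter Tap1 at 0.45 ± 0.12 and the MHC gene H2-K1 at 0.52 ± 0.16. Of 21 cholesterol synthesis genes 20 were lower, by -0.25 on average, with Idi1 at -0.51 ± 0.14, Fdft1 at -0.34 ± 0.13 and Nsdhl at -0.33 ± 0.13. Of 26 Purkinje cell markers 23 were lower, by -0.29, with the ryanodine receptor Ryr1 at -0.55 ± 0.19, the LIM factor Lhx5 at -0.52 ± 0.18 and Kcng4 at -0.56 ± 0.27. No single gene passed (n = 6 and 5, with 5 usable KI mice for Ryr1), and Ryr1 was at -0.31 without WT replicate 23.

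The interferon list had a mean log2 ratio of 1.17 ± 0.42 (SD, n = 6) in KI and 0.72 ± 0.44 (SD, n = 5) in WT mice. Camera's adjusted p was 1.85e-15 for interferon, 1.37e-07 for cholesterol synthesis and 0.000514 for Purkinje cell genes, and with an estimated correlation adjusted p = 0.285, 0.285 and 0.935. Over all probes limma called 0 of their members; adjusted over the list alone there were 2 higher interferon genes, 1 lower cholesterol gene and 0 Purkinje genes. No removal of 1 mouse ended these 3 calls. They did not stand on every slide. The interferon list differed by -0.09 on slide 5, 0.81 on slide 7 and 0.66 on slide 8, the cholesterol list by 0.04, -0.22 and -0.41, and the Purkinje list by 0.06, -0.50 and -0.48. The values were 0.33, -0.21 and -0.20 with slide as a block (adjusted p = 1.62e-07, 1.11e-06 and 0.00135), where Idi1 passed (-0.48, adjusted p = 0.0345).

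Slide 5 held KI replicate 21 and WT replicate 20, which lay apart from their groups. In interferon genes KI 21 was at 0.31 where the other KI mice averaged 1.34 ± 0.07 (SD, n = 5), and WT 20 was at 1.36 where the other WT mice averaged 0.56 ± 0.30 (SD, n = 4). Without these 2 mice, an alternative chosen because they stood apart and so no independent evidence, limma called 147 probes at week 11, 62 higher and 85 lower. They included Irf7 (1.34 ± 0.23), Irf9 (1.10 ± 0.16), H2-K1 (0.81 ± 0.13), Opn3 (-1.61 ± 0.18) and Idi1 (-0.74 ± 0.12), named after their values were seen, and the interferon list differed by 0.78. The count was 16 without KI 21 alone, 9 without WT 20 alone and 1 without WT 23.

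**Figure D3:**
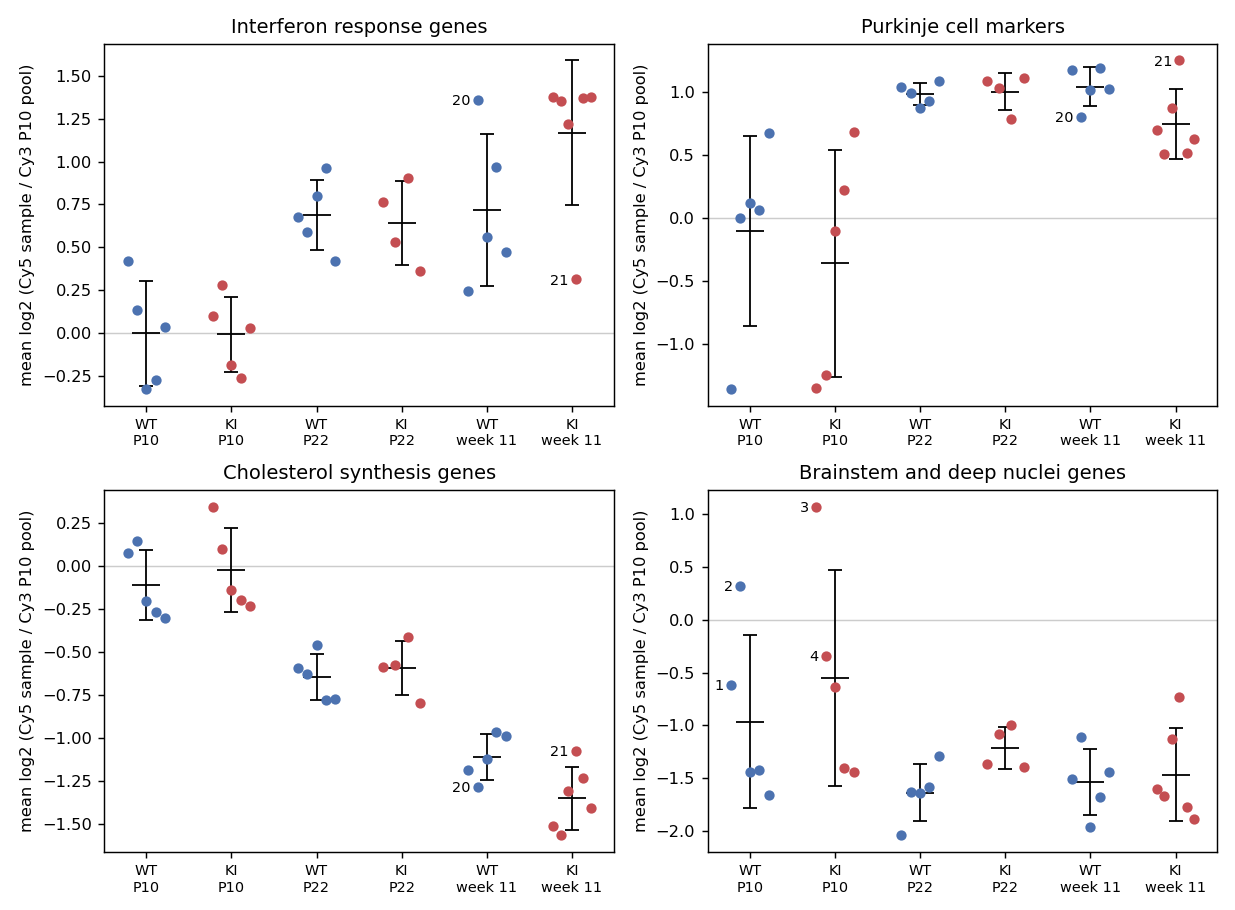
Mean log2 ratio of 4 gene lists per mouse, by genotype and age, with mean and SD of 4 to 6 mice; numbers mark week 11 mice 20 and 21 and P10 mice 1 to 4. In interferon genes at week 11, KI 21 is at 0.31 and WT 20 at 1.36.

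Of the week 11 calls at camera's preset correlation, those of Bergmann glia, myelin and choroid plexus genes also ended with an estimated correlation (adjusted p = 0.285, 0.935 and 0.935), and no member of the 3 lists passed. Bergmann glia and astrocyte markers differed by -0.26 (15 of 18 lower), with glutamine synthetase Glul at -0.67 ± 0.23 (5 usable KI mice), the water channel Aqp4 at -0.56 ± 0.23 and connexin 43, Gja1, at -0.42 ± 0.17. Myelin genes differed by -0.29 (16 of 20 lower), with Aspa at -0.55 ± 0.25 and Ugt8a at -0.76 ± 0.35. Choroid plexus genes, a sign of how much choroid plexus was in the sample, differed by -0.66 (10 of 11 lower), with Col8a1 at -0.57, Clic6 at -0.76 and Ttr at -1.85 ± 1.38 (5 usable KI mice). The adjusted p values at the preset correlation were 0.00502, 0.00959 and 0.0227. Limma called 0 members of each over all probes and 0 adjusted over the list alone.

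The Bergmann glia call ended without KI replicate 16 (-0.20, adjusted p = 0.0548) and the myelin call without KI 34 (-0.235, 0.147), WT 23 (-0.24, 0.0758) or, at a similar mean, WT 18 (-0.29, 0.0526). The choroid plexus call rested on single mice: the mean of -0.66 was -0.19 without WT 20 (0.884), -0.43 without WT 23 (0.252) and -0.36 without both mice 20 and 21 (0.57). Without WT 20, Col8a1 was at -0.26, Clic6 at -0.50 and Ttr at -0.73, and Ttr was at -1.15 without WT 23 and at -2.80 without WT 18. It also ended at a similar mean without KI 16 (-0.57, 0.0548), KI 22 (-0.56, 0.0576) or KI 34 (-0.59, 0.147) and with scan day as a block (-0.54, 0.066), and with Agilent's own log ratio (-0.70, 0.0693). On slides 5, 7 and 8 the Bergmann glia list differed by 0.04, -0.31 and -0.34, the myelin list by 0.01, -0.30 and -0.57, and the choroid plexus list by -0.41, -1.98 and -0.11. Limma called 0 of 35254 probes at week 11, with 1766 at an unadjusted p under 0.05 where chance gives 1763; the smallest adjusted p over all probes was 0.23. Among genes, with 1 probe each, the smallest p values belonged to Mela (-0.63, adjusted p = 0.367), Mlkl, the effector of necroptosis (0.43, 0.477), Dkk3 (0.60, 0.541), Slco1a5 (-0.43, 0.541) and Xdh (-0.64, 0.541), for which 6 of 6 KI mice lay below every WT mouse.

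The remaining lists were not called at week 11. Granule neuron markers differed by -0.08 (adjusted p = 0.796), granule precursor genes by -0.01 (0.796), cell cycle genes by 0.04 (0.705), inhibitory interneuron markers by -0.01 (0.796), oligodendrocyte precursor markers by -0.12 (0.729), microglia genes by -0.09 (0.4), cytosolic heat shock genes by -0.02 (0.912), and unfolded protein stress genes by -0.09 (0.372). SAGA complex genes differed by 0.02 (0.729), other ataxia genes by -0.10 (0.729), oxidative phosphorylation genes by -0.06 (0.729), insulin-like growth factor genes by -0.11 (0.729), immediate early genes by -0.04 (0.796), erythrocyte genes by -0.18 (0.796), brainstem genes by 0.05 (0.768), endothelial genes by -0.08 (0.729) and meningeal genes by -0.20 (0.303). Slide as a block called 2 of these lists, cell cycle genes (0.17, adjusted p = 0.000284) and microglia genes (-0.13, 0.0382), and scan day as a block neither (0.079 and 0.066).

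Averaged over the 3 ages, camera at its preset correlation called lower means of Purkinje cell, Bergmann glia and granule neuron markers in KI mice and higher means of interferon response and brainstem genes, and none of these 5 lists with an estimated correlation. Purkinje cell markers differed by -0.20 (18 of 19 lower), with Ryr1 at -0.36 ± 0.11, Lhx1 at -0.44 ± 0.21 and Lhx5 at -0.21 ± 0.11. Bergmann glia markers differed by -0.21 (12 of 14 lower), with Aqp4 at -0.47 ± 0.14, Fabp7 at -0.55 ± 0.20 and Gja1 at -0.21 ± 0.10. Granule neuron markers differed by -0.28 (9 of 10 lower), with Chn2 at -0.42, Zic1 at -0.60 and Tiam1 at -0.20, which was -0.13 without WT P22 replicate 26. Interferon genes differed by 0.14 (18 of 20 higher), with Tap1 at 0.19, H2-D1 at 0.15 and H2-K1 at 0.17, a mean that comes from week 11 (0.44) and not from P10 (0.03) or P22 (-0.05), and brainstem genes by 0.27 (16 of 18 higher), with Hoxa4 at 0.44, the serotonin enzyme Tph2 at 0.85 and Slc17a6 at 0.50.

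The adjusted p was 0.00304, 0.00304 and 0.03 for Purkinje, Bergmann glia and granule neuron markers, and 0.00757 and 0.03 for interferon and brainstem genes; with an estimated correlation adjusted p = 0.785, 0.304, 0.785, 0.785 and 0.785. Limma called 0 of their members over all probes; adjusted over the list alone there was 1 lower gene in each of the Purkinje, Bergmann glia and granule lists. Limma called 0 of 33114 probes, with 4228 at an unadjusted p under 0.05 where chance gives 1656, and the smallest adjusted p over all probes was 0.126. Among genes, with 1 probe each, the smallest p values belonged to Kdf1 (adjusted p = 0.167; no size is given, since no WT P22 array was well above background), 9530051G07Rik (-0.40), Gm3696 (0.80), Ahnak (-0.40) and Psmd3 (0.22, adjusted p = 0.189). With slide or scan day as a block the WT P22 side of the average rests on WT 26, since slide 6 and its scan day held only WT P22 mice. That array had the lowest array weight, 0.261. Slide as a block put interferon genes at 0.04 and Bergmann glia markers at -0.19, neither of them called, Atxn7 at -0.58 and Tiam1 at -0.37. On slide 7 the P22 pair differed by -1.11 in Atxn7 and -1.04 in Tiam1. WT 26 was at 1.37 in Atxn7, where the other WT P22 mice lay at 0.41 to 0.70. Scan day as a block put the 2 lists at 0.03 and -0.18, again without a call. The blocks put other ataxia genes at -0.17 and -0.16 and immediate early genes at -0.24 and -0.21. Calls lost or gained in these blocked fits cannot be told apart from the values of WT 26. Median centring ended all 5 calls (adjusted p = 0.0804 to 0.177). The granule neuron and brainstem calls also ended from the Cy5 channel alone (-0.14, adjusted p = 0.0553, and 0.18, 0.787), with the mean of all probes of a gene (-0.20, 0.0989, and 0.23, 0.0843) and with outlier spots kept (0.0788 each). Agilent's own log ratio ended that of brainstem genes (0.25, 0.225), and leaving out mice 20 and 21 (0.0547) or mice 7, 8, 20 and 21 (0.0758) that of granule neuron markers. Without KI P22 replicate 13 the interferon call ended (adjusted p = 0.0659).

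The brainstem mean of 0.27 fell to 0.13 without KI replicate 3 (adjusted p = 0.323). At means of 0.21 to 0.29 its call also ended without KI replicate 12 (0.0568), 13 (0.0659), 17 (0.0505), 19 (0.0832) or 21 (0.0938), or WT replicate 5 (0.0632), 7 (0.0813), 10 (0.182), 23 (0.0545), 26 (0.0808) or 32 (0.0749). The granule neuron mean of -0.28 was -0.18 without KI replicate 3 (0.175) or 4 (0.264), and at means of -0.28 to -0.20 its call also ended without KI replicate 6 (0.0865), 11 (0.112), 13 (0.149), 17 (0.184) or 21 (0.0678), or WT replicate 5 (0.0632), 10 (0.182), 18 (0.0528) or 26 (0.0808). The Purkinje mean of -0.20 was -0.13 without KI replicate 3 (0.0496) or 4 (0.03). Without KI P10 replicate 8, 13 probes were called, among them Gm3696 (adjusted p = 0.00753), and without WT P10 replicate 7 there were 6.

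The series asks where the course over time differs between genotypes. By its own criterion 3 of 1354 tested probes passed at an unadjusted p under 0.001, with 69 under 0.05 where chance gives 68. They were Mela, the circadian clock gene Per2 and Cpsf4l, with limma interaction p values of 3.24e-05, 0.000232 and 0.000644. KI minus WT at P10, P22 and week 11 was 0.14, 0.36 and -0.63 for Mela, -0.33, -0.83 and 0.66 for Per2, and -0.18, 0.49 and -0.88 for Cpsf4l. The smallest adjusted p within those probes was 0.0439. The count was 1 without KI P22 replicate 11 or 13, 6 without WT P10 replicate 1, 7 without KI week 11 replicate 21 and 10 without WT week 11 replicate 20. Processing moved it further, to 29 with slide as a block, 22 with array weights and 12 with scan day as a block. It was 1 with scale normalisation, without background subtraction and in the value table.

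Over all 33114 probes limma's interaction test called 0, with 1653 at an unadjusted p under 0.05 where chance gives 1656. The change of the genotype difference called 0 of 33171 probes from P10 to P22 (1411 at an unadjusted p under 0.05) and 0 of 33187 from P22 to week 11 (1851) by limma. Of the lists, meningeal genes changed between P10 and P22 by 0.54 (adjusted p = 0.0214; 0.948 with an estimated correlation). Interferon genes changed from P22 to week 11 by 0.49 (adjusted p = 6.04e-08; 0.77 with an estimated correlation), and cholesterol synthesis genes by -0.31 (adjusted p = 0.00283; 0.822 with an estimated correlation). All of these changes include P22, where slide and genotype were nearly the same split.

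The genotype difference did not follow normal maturation beyond the range that permutations of genotype within age gave. Those permutations exchange mice across slides, whose arrays correlate (0.427), so slide effects are part of that range. Across genes, which are not independent replicates, KI minus WT at week 11 had a correlation of -0.21 with the WT step from P10 to P22 (permutation p = 0.21). The correlation was 0.16 at P10 (permutation p = 0.23) and -0.22 at P22 (permutation p = 0.36). From the Cy5 channel alone the P10 value turned to -0.126 (permutation p = 0.38). In the Cy3 channel, where every array carries the same pool, limma called 0 probes between KI and WT arrays at P10 (127 at an unadjusted p under 0.05), 11649 at P22, of which 10107 were higher on KI arrays, and 0 at week 11 (3133 at an unadjusted p under 0.05). The P22 count was 196 with slide as a block.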

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

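Among the tests in this part, those of exchanged labels, of an effect of slide 5, of an immune response in WT replicate 20 alone, of adjacent tissue and of a younger stage, the exclusions of mice, and the counts of splits within slides were chosen after the results were seen; the tests of the Cy3 channel and the other counts of splits were planned.

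At week 11, KI replicate 21 and WT replicate 20 lay on the other genotype's side in interferon response genes (0.31 and 1.36). KI 21 lay nearer to the other genotype in 19 of 23 lists and WT 20 in 11 of 23. These counts say little about labels, since KI 21 lay above the means of both groups in some lists. It was at -0.733 in brainstem genes (other KI mice -1.609, other WT mice -1.642) and -1.905 in cell cycle genes (-2.582 and -2.453). In cholesterol synthesis genes it was at -1.075 (-1.405 and -1.066), near the WT mice. Its array had the lowest median Cy5 signal of all arrays (135.1) and an array weight of 0.379. Averaged over ages, 13 probes were called without KI P10 replicate 8 and 6 without WT P10 replicate 7. A common effect of slide 5 on the week 11 mice is argued against by its 2 other mice, WT 18 and KI 19, whose mean deviation in interferon genes in the directions of the pair was -0.134, but they went apart, WT 18 lying -0.419 from the WT mice of other slides, against the direction of WT 20 (0.697), and KI 19 lying -0.151 from the KI mice of other slides (SD 0.012), in the direction of KI 21 (-1.055), so a small effect in KI mice and an effect on the arrays of the pair alone stay open. An immune response in WT 20 stays open too, since its microglia genes lay -0.12 from the other WT mice, within their spread. Exchanged labels at week 11 cannot be told apart from unusual mice. The test used 20 probes of chromosome 14, which carries Atxn7, chosen from the P22 mice alone, several of them reading the same gene. WT 20 scored -0.73, on the KI side of the midpoint of -1.101, and KI 21 scored -1.1, a difference of 0.373. Read without a margin, KI 21 barely lay on the side of its own label, which goes against an exchange. A margin above the SD of a group was required by a rule set with the value in view, and by it the test cannot tell. At P10 the same probes put KI 8 at -1.17 and WT 7 at -0.18, 0.983 apart and each beyond the midpoint of -0.44, but KI 9 lay below it too. Of the 25 single exchanges that of KI 8 and WT 7 gave 1 called probe, while that of KI 8 and WT 1 gave 4731. The second condition set for this pair was therefore not met. The count of 4731 follows slide 1, so this condition says little about labels. An exchange at P10 stays undecided, and the labels are kept as given.

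In the P10 mice of slide 1, brainstem genes were higher by 1.44 (exact permutation p = 0.00476, 4 mice against 6) and granule neuron markers differed by -1.56 (exact permutation p = 0.0143) from the other P10 mice, where WT 2 at 0.074 lay within the range of the others in granule neuron markers. Slide 1 was singled out after its values were seen, so these p values are no independent evidence. For these 2 lists a hybridisation or scan effect common to both channels is argued against, since they differed by -0.068 and 0.03 in Cy3, but Cy3 did differ for other lists, opposite in sign to the ratio, in erythrocyte (-0.54, exact permutation p = 0.00476), cholesterol synthesis (-0.145, 0.00476), SAGA complex (0.12, 0.0238), other ataxia (0.24, 0.0429) and meningeal genes (0.29, 0.0429), and an effect on the Cy5 labelling alone stays open. For a younger stage the lists go both ways, so it stays open. Cell cycle genes, which fall with age, differed by -1.223 (exact permutation p = 0.00952), and myelin genes, which rise from P10 to P22, were higher, both against it. Oligodendrocyte precursor markers and cholesterol synthesis genes, which fall in that step, were higher by 0.904 and 0.389 (exact permutation p = 0.00476 each). Granule neuron and Purkinje cell markers, which rise in it, were lower. More tissue from next to the cerebellum stays open as a candidate explanation: myelin genes were higher by 1.035 (exact permutation p = 0.00476) and Purkinje cell markers differed by -1.27, but the list was read after its direction was known, and most myelin genes are also expressed in the cerebellum. No difference in age or genotype that the design names separates these mice.

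The Cy3 reference channel differed between KI and WT arrays at P22 in 11649 probes although every array carries the same pool. The P22 genotypes lie on different slides except for 1 pair on slide 7, and the Cy3 difference of the other slides did not recur there (r = 0.121 across 34086 probes, which are not independent; median absolute differences 0.30 and 0.09), which is consistent with a difference between slides. The Cy3 difference also followed the Cy5 intensity difference of the same slides (r = 0.862 across probes), so sample signal in the reference channel stays open, and a batch effect on both channels would give that value too. Slide 7 has 1 array of each genotype, which limits the first test. No biological explanation was tested.

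Single mice stood apart from the rest of their group in 24 of 386 groups tested, 6.22%, where chance gives about 1 in 20. KI week 11 replicate 21 did so 7 times and WT P22 replicate 26 did so 6 times. KI 21 was at 0.314 in interferon response genes, 0.182 in Gja1, 1.273 in H2-K1, -0.412 in Col8a1, 0.873 in Clic6, -1.546 in Gm3696 and 2.741 in Chn2, in each of the 7 nearer to the mean of the WT mice than to that of the other KI mice. WT P22 replicate 26 was at 0.65 in other ataxia genes, -0.002 in oxidative phosphorylation genes, -1.377 in Mcub, 1.937 in LOC629147, 0.499 in Xdh and 0.528 in Cldn11. WT week 11 replicate 20 was at -0.037 in Kdf1 and -2.246 in Cyp51. KI week 11 replicate 19 was at 0.511 in Xdh, and KI P22 replicate 17 was at -0.258 in Lig4. Among P10 mice, KI 9 was at 0.642 in Tiam1, KI 3 at 1.572 in Hoxa4, WT 1 at -4.947 in Gabra6, and WT 10 at 0.409 in Fos and 0.836 in LOC629147. Among WT P22 mice, replicate 27 was at -3.41 in Mki67 and replicate 30 at 0.352 in Sdha.

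By camera's test of the change itself at its preset correlation the genotype difference changed with age in 3 lists, and in none with an estimated correlation (adjusted p = 0.948, 0.77 and 0.822) or by fry. Meningeal genes changed by 0.538 from P10 to P22, interferon response genes by 0.49 from P22 to week 11, and cholesterol synthesis genes by -0.31 from P22 to week 11. Each change includes P22, where genotype and slide are nearly the same split. The P10 meningeal difference also fell from -0.34 to -0.13 in size without KI replicate 4.

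Other splits of the same mice into groups of the same sizes show where a random grouping of mice can be excluded. For the WT steps it can: 1 of 100 splits, the real one, gave as many probes as the 10444 from P10 to P22 (highest other 2536), and 1 of 100 gave as many as the 597 from P22 to week 11 (highest other 8). These splits take no account of slide, whose arrays correlate (0.427), and no slide held WT mice of both P10 and P22 and only slide 7 those of both P22 and week 11, so they do not separate age from slide. The Cy3 difference at P22 also stood above the other splits (1 of 100, real 11649, highest other 11021). For KI against WT the real counts were 0, which every split reaches (100 of 100), so the splits decide nothing there and show only how many probes other groupings call: at P10 (highest other 7339), at P22 (highest other 1), at week 11 (highest other 261), averaged over ages (highest other 197), for the change from P10 to P22 (highest other 4868), for that from P22 to week 11 (highest other 74), and for the interaction (highest other 4156). Likewise for Cy3 at P10 and week 11 the real counts were 0 (highest other 569 and 3964). By the criterion of the series 24 of 100 splits gave at least the real 3 (highest other 241).

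Splits that call many genes point to a structure of the samples. The split with 7339 probes at P10 puts the 4 mice of slide 1 and KI 6 against the rest, so it follows slide 1, and with slide as a block 589 probes were called, which 2 of 36 splits within slides reached (highest other 2303). The split with 261 probes at week 11 exchanges KI 21 and WT 20, the highest of 30 single exchanges, where the second highest gave 10. With slide as a block 23 probes were called at week 11, which 26 of 36 splits within slides reached (highest other 1288). Neither blocked count excludes chance. The numbers of called lists were counted in 6 comparisons and not for the changes between ages. Between KI and WT chance cannot be excluded where lists were called. At P10 92 of 100 splits reached the real 3 (highest other 13), and at week 11 the real 6 were reached by 19 of 100 (highest other 10). Averaged over ages 62 of 100 reached the real 5 (highest other 13). At P22 the real count was 0, which decides nothing (highest other 8). These splits exchange mice across slides, so some of them follow slide 1 at P10. In WT 19 of 100 splits reached the real 10 from P10 to P22 (highest other 14). From P22 to week 11 the real 5 were reached by 43 of 100 (highest other 11). Splits that leave most WT mice of an age together keep part of the age difference and can call lists through it. For the WT steps these counts therefore decide nothing. Within slides and with slide as a block, 23 of 36 splits reached the real 6 lists at P10 (highest other 11) and 4 of 36 the real 8 at week 11 (highest other 9), so chance cannot be excluded there either.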

How the results depend on the processing

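Among the tests in this part, scan day as a block for the gene lists, a random slide block, no minimum of usable arrays, keeping outlier spots and leaving out mice 1 to 4, 7, 8, 20 and 21 were chosen after the result was seen. Mice 7, 8, 20 and 21 were singled out because their expression stood apart, so counts without them are not independent evidence.

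Of all values under the alternatives set beforehand 4592 stayed on the same side, 285 became weaker, 65 stronger, 102 moved and 4 reversed; of those added later 974 stayed, 33 became weaker, 22 stronger and 27 moved. The cause of the changes below was not tested. The reversed values were oxidative phosphorylation genes in WT from P10 to P22 with median centring (-0.0757) and Uqcrc2 in the same step in Cy5 alone (-0.034), with slide as a block (-0.0367) and with scan day as a block (-0.0142). No paired analysis was possible because no replicate number occurs in more than 1 group; mice of both genotypes that share a slide were compared with slide as a block. Only the arrays of the groups compared gives no value for averages over ages, interactions and the criterion of the series.

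With slide as a block the counts of probes were 589 at P10 (291 higher, 298 lower), 2371 at P22 (495 and 1876), 23 at week 11, 1646 averaged, 1614 for the change from P10 to P22, 1058 for that from P22 to week 11, 1135 for the interaction, 29 by the criterion of the series, 5293 and 1198 for the WT steps, 6 lists at P10, and in Cy3 196 at P22 and 29 at week 11. With scan day as a block they were 1133 at P22, 628 averaged, 534 and 367 for the changes, 141 for the interaction, 12 by the criterion of the series, 3781 for WT from P10 to P22, and 6 lists in that step. In both of these fits the WT P22 side rests on WT 26, so counts that include P22 cannot be told apart from the values of that mouse. As a random block slide gave 16 at P10, 1 at week 11, 15 averaged, 302 for WT from P22 to week 11 and 5 by the criterion of the series.

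Array weights gave 875 at P22, 74 at week 11, 477 averaged, 28 for the change from P22 to week 11, 22 for the interaction, 22 by the criterion of the series and 2743 for WT from P22 to week 11. Cy5 alone gave 3853 at P22 (85.8% higher, median of all genes 0.158), 1564 averaged, 372 for WT from P22 to week 11, 7 by the criterion of the series, 6 lists at P10, Atxn7 at P22 at -0.151 (exact permutation p = 0.603) and a maturation correlation at P10 of -0.126; the median of all genes was 0.14 and -0.146 for the changes between ages. Median centring gave 1126 for WT from P22 to week 11 (79.9% higher against 53.6%), 0 lists at P10, 1 at P22 and 0 averaged. Scale normalisation gave 81 in that WT step (66.7% higher) and 1 by the criterion of the series. The value table gave 1515 and 127 for the WT steps (23.6% higher in the second) and 1 by that criterion, as did no background subtraction (1) and adjusting within its probes (1). Offset 16 gave 1 at week 11, only the arrays compared gave 29 at P22, and genes in place of probes gave 6502 for WT from P10 to P22. No minimum of arrays gave 1 at P10, and keeping outlier spots gave 5 lists at P10 and 1 at P22.

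With an estimated correlation camera called 0 lists at P10, week 11, averaged and in both WT steps, and fry called 0 at P10, 0 at week 11, 0 averaged and 1 in WT from P22 to week 11. The mean of all probes of a gene gave 1 list at P10 and 1 at P22.

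Without mice 20 and 21 the counts were 147 at week 11 (62 higher, 85 lower), 12 averaged, 5 for the change from P22 to week 11, 5 for the interaction and 18 by the criterion of the series. Without mice 7 and 8 they were 17 averaged and 6 lists at P10, and without all 4 they were 8 at P10, 151 at week 11, 26 averaged, 3 for that change, 6 for the interaction, 15 by the criterion of the series and 6 lists at P10. Without mice 1 to 4 they were 90 at P10 (81 higher, 9 lower), 9 averaged, 6 by the criterion of the series and 0 lists at P10.

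Leaving out 1 mouse at a time gave 0 to 11 probes at P10 (11 without WT 1), 0 to 0 at P22, 0 to 16 at week 11 (16 without KI 21, 9 without WT 20, 1 without WT 23), 0 to 13 averaged (13 without KI 8, 6 without WT 7, 3 without WT 20, 1 without KI 17, WT 10 or WT 33), 0 to 0 for the change from P10 to P22, 0 to 2 for that from P22 to week 11 (2 without KI 21, 1 without KI 19 or WT 23), 0 to 1 for the interaction (1 without WT 23), 1 to 10 by the criterion of the series (1 without KI 11 or KI 13, 7 without KI 21, 6 without WT 1, 10 without WT 20), and 9131 to 10159 and 251 to 905 for the WT steps (905 without WT 26, 251 without WT 30, 329 without WT 31, 267 without WT 32, 324 without WT 33). Lists called were 0 to 7 at P10 (0 without KI 3 or KI 4, 5 without KI 6, 7 without KI 8, 6 without KI 9 or WT 1), 0 to 0 at P22, 4 to 6 at week 11, 2 to 7 averaged (3 without KI 3, 17 or 21 or WT 5, 10 or 26, 2 without KI 13), and 8 to 12 and 4 to 7 in the WT steps. Atxn7 lay at -0.39 to -0.117 at P10, -0.667 to -0.389 at P22 and -0.282 to -0.0314 at week 11, and the maturation correlation at 0.092 to 0.201, -0.267 to -0.112 and -0.274 to -0.093.

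Signal over background limits the dim probes: 67.7% to 89.7% of the Cy5 spots of an array were well above background, and the log2 ratio of the others is pulled towards 0 by the offset.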

Other observations

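The tests in this part were chosen after the result was seen.

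Without the 4 mice of slide 1, limma called 90 probes at P10, 81 higher and 9 lower in KI mice. Among them were Dbh (1.55), Slc6a2 (2.31), Ache (1.36), Hsp90ab1 and Stip1, picked by hand after their values were seen and with no test of enrichment. In the same fit camera called 0 of the 23 lists, and 3 KI and 3 WT mice remained.

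A hypothesis was tested that differences in expression linked to the targeted locus mark the KI mice. On each of 20 chromosomes the 20 probes that best separated the P22 genotypes were chosen and read at the other ages. The probes of chromosome 14, which holds Atxn7, had the largest mean difference over P10 and week 11, 0.419, and the next chromosome, 2, had 0.168. At P10 the chromosome 14 probes differed by 0.38 (exact permutation p = 0.214, adjusted over chromosomes 0.388) and at week 11 by 0.46 (exact permutation p = 0.026, adjusted 0.52), so neither age passes alone. Whether differences that travel with the locus, such as flanking sequence kept from another strain, mark the mice stays undecided, and sequence was not measured. The 20 probes cover 11 genes and are not independent, since several of them read Gm10413 and several 4930555G01Rik. Atxn7 is at place 102 of 851 protein-coding genes in order along the chromosome. Those 2 genes are at places 9 and 34, while Ear6 (450), Pcdh8 (778) and Klhl1 (786) lie far from Atxn7. The probes were chosen at P22, where genotype and slide are nearly the same split.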
